A study of Rattus norvegicus with 4 samples.

How the data were processed

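Kidney RNA was measured in 4 groups of male rats aged 9 weeks, made of 2 inbred strains and 2 prenatal treatments. Per the labels, the strains were the spontaneously hypertensive rat (SHR) and Brown Norway (BN), and the animals had been exposed to nicotine or to saline before birth. Total RNA was extracted with Trizol, per the labels' protocols. Equal amounts of RNA from the animals of a group were pooled and each pool was hybridised to 1 Affymetrix RAE-230A array, per the series' design text. The pools held 13 animals in the SHR nicotine group and 12 in each of the other 3 groups, 49 animals in all.

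The deposited values are array signal intensity on a linear scale, 1 value for each of 15923 probe sets on each array. The authors made them with MAS5, per the submitters' processing notes; its version and settings are not given in the sources used here. The 2% trimmed mean was 150.0 on every array, so the intensities had been scaled to a common level before deposit and were used as deposited. The 57 Affymetrix control probe sets were left out of all comparisons. Of the other 15866 probe sets, 12783 had 1 gene symbol in the platform annotation, 312 had several and 2771 had none; gene names were updated through the gene identifier to the current RefSeq symbols. Probe sets with several symbols or none were not named. The named probe sets covered 10411 genes, and a gene with more than 1 probe set was represented by the one with the highest mean signal. No genome was used here, so no coordinates are given.

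Signals below 44.5, the 40th percentile of all values, were raised to that floor before taking log2, because MAS5 signals near background have no stable ratio. A gene was called measured in a comparison if the higher of its values was at least 89.0, which is 2 times the floor. Where a gene lay below the floor in one group, the fold is a lower bound and is written as "at least". The intensity scale is arbitrary, so levels of different genes were not set against each other.

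With 1 pool per group, nicotine against saline within a strain, and SHR against BN within a treatment, have no replicate check. For those 4 comparisons the sizes of the log2 ratios were described, with counts at 1.5, 2 and 3 fold, and no p-value was computed. Averages over the design were tested with limma 3.58.1 in R 4.3.3: an additive model of strain and treatment over the 4 arrays, lmFit and eBayes with an intensity trend, and Benjamini-Hochberg adjustment at 0.05. The model leaves 1 residual degree of freedom, which holds array noise together with any nicotine response that differs between strains. Its p-values rest on the spread between these 4 arrays, not between animals. Most of that spread was borrowed by eBayes from genes of similar signal, with 19.33 prior degrees of freedom for strain and 13.33 for nicotine. Genes entered if the higher of their 2 group means was at or above 89.0 on the log2 scale.

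Lists of marker genes (11) and of pathways (21) were fixed before the data were examined. A list's median log2 ratio was placed among the medians of 10000 random lists of the same size, matched in 10 bins of mean signal, and lists outside the central 95% are described by that position only. For the tested averages, members past the threshold were counted over all genes and again adjusted over the list alone, with no adjustment for the number of lists.

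Genes to name were chosen by a rule fixed before the data were examined. For nicotine in each strain the rule takes the 10 genes with the largest positive and the 10 with the largest negative log2 ratio. For both strains together it takes the 5 genes with the largest shared shift in each direction, and 5 in each opposite direction. For strain it takes the 10 largest in each direction past the threshold with the same direction under both treatments. Genes taken for 1 strain or for the strain difference had to have their other measured probe sets, where there were any, moving the same way. In the strain comparison under saline, no gene named for the strain difference had another measured probe set. Of those taken for nicotine in 1 strain, only Glrx had one there. The named genes therefore rest on a single measured probe set in nearly all cases. Of each list described, the 2 to 4 members with the largest ratio in either direction are named; for the strain average they were taken among members past the threshold over all genes, a restriction added after the values were seen. Named in addition are genes of the angiotensin system, Cd36, Nphs1 and Wt1 where measured. Some genes of this rule are not reported. Any other gene named was chosen after its values were seen, and this is said beside it.

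The limma and gene list steps were tested on simulated arrays built from 7409 real probe set means, with noise matched to signal level and 200 changed genes. For SHR against BN averaged over treatments, 50 of 67 genes changed 1.5-fold were recovered, 67 of 67 changed 2-fold and 66 of 66 changed 3-fold, with 3 false calls among 7209 unchanged probe sets. For nicotine against saline averaged over strains, 52 of 67, 67 of 67 and 66 of 66 were recovered, with 21 false calls. With no gene changed, both contrasts gave 0 calls. The simulated genes of a signal level shared the same noise, and no response differed between strains. These recoveries therefore do not give the power of the nicotine test on the real arrays. There, the gene Uchl1 averaged 2.15-fold higher under nicotine and had an adjusted p of 0.0979 with limma. For nicotine against saline in SHR, a list of 20 genes shifted by 0.20 on the log2 scale lay above the central 95% in 48 of 50 simulations and a list of 10 in 40 of 50; at a shift of 0.1 these were 29 of 50 and 20 of 50. Unshifted lists of 20 lay outside in 3 of 50 and lists of 10 in 2 of 50. The simulated noise was independent between probe sets, so these counts do not cover lists whose genes vary together.

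Alternatives covered quantile normalisation, median centring and cyclic loess, floors at the 20th and 60th percentile, log2(value + 16) without a floor, other filters, means over probe sets, probe sets in place of genes, other fold thresholds, eBayes without a trend, models with a single factor and fits without each array. Statistics other than limma used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.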

Results

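The data consist of 4 arrays of kidney RNA, 1 for each of SHR nicotine, SHR saline, BN nicotine and BN saline, where SHR is an inbred rat with inherited high blood pressure and BN a strain with normal blood pressure. The series addresses how nicotine before birth affects kidney gene expression in male rats of 9 weeks. Each array carried RNA pooled from 12 or 13 animals, so no comparison within a strain has a replicate, and the number of arrays limits the precision of all values. Between 58.9% and 60.7% of probe sets reached the floor on each array, and 5697 genes were measured on at least 1 array. Across these genes the SD of the log2 ratio was 0.21 between the SHR pools and 0.20 between the BN pools, against 0.36 between strains under either treatment.

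In SHR, the gene furthest above its saline level in the nicotine pool was Klf10, a transcription factor induced by TGF-beta, with a signal of 137.0 against 41.3, at least 3.08-fold higher. Mmp14, a membrane-bound matrix metalloproteinase, was 2.33-fold higher (105.1 against 45.2), and C1qbp, a mitochondrial matrix protein, was 2.01-fold higher (602.4 against 300.4). Zfp638 was 2.20-fold lower under nicotine (86.9 against 190.8) and Tp53i13 was 2.08-fold lower (49.7 against 103.3). Gk, the glycerol kinase that starts the use of glycerol, was 1.87-fold lower (230.4 against 429.7), and Tnfrsf11b, the decoy receptor osteoprotegerin, was 1.83-fold lower (80.0 against 146.5).

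Of 5470 genes measured in SHR, 59 were at least 1.5-fold higher and 43 at least 1.5-fold lower under nicotine, and 5 and 2 passed 2-fold. The other 2 genes past 2-fold were Zfp267, at least 2.09-fold higher, and LOC102550950, at least 2.0-fold higher. The next largest positive ratios belonged to Tlcd3b, Ddn, Osbpl11, Mrpl1 and the receptor tyrosine kinase Tyro3, from 1.96-fold down to 1.86-fold. The next largest negative ratios belonged to Cinp and Wdr33, both 1.91-fold lower, Ube2r2, Grm8, C2cd5 and Mob2. With means over all probe sets of a gene the Grm8 ratio was much smaller, as given in the part on processing. For Klf10 and C1qbp the SHR saline pool was the lowest of the 4 arrays: both BN pools read 143.3 and 147.3 for Klf10, and 642.6 and 604.1 for C1qbp.

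Of 13 measured genes of interferon response and antigen presentation, 11 were higher, with a median log2 ratio of 0.19 at percentile 99.9 of random lists. Ifit1, an interferon-induced inhibitor of translation, stood at 0.54, and Stat2, which carries the interferon signal, and Cd74, the invariant chain of class II molecules, both at 0.30. The immune cell markers, 5 of which also stand in the interferon list, had a median of 0.14 (percentile 98.5), with Cd74 first and Lyz2 and Fcer1g at 0.21. Fatty acid oxidation genes had a median of 0.06 (percentile 97.9, 20 of 26 higher), with Ehhadh at 0.31 and Pdk4 at -0.39. Xenobiotic metabolism genes had a median of 0.07 (percentile 97.9), led by the glutathione transferase Gstm1 at 0.61 and the cytochromes Cyp2c11 at 0.38 and Cyp2e1 at 0.37. The SHR candidate genes, 7 of them measured, had a median of 0.25 (percentile 99.9), again with Gstm1 first, followed by Acsm3 at 0.28. In all, 5 of 30 lists lay above the central 95% of random lists and 0 below it. Chance would put 1.5 outside if genes and lists were independent. Some of these lists share genes, and lists of genes that vary together between single pools could exceed that number without nicotine. No list member other than Mmp14 and Gstm1 was 1.5-fold apart. The interferon and SHR candidate lists stayed outside the central 95% in all 4 alternatives tried on lists. Fatty acid oxidation stayed outside it in none, at percentiles from 87.1 to 97.1, and immune cells and xenobiotic metabolism fell within it in 1 and 2.

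In BN, Icam1, the adhesion molecule that binds leukocytes, was at least 2.84-fold higher in the nicotine pool than in the saline pool (126.2 against 18.5). Uchl1, a ubiquitin hydrolase of neurons and injured podocytes, was at least 2.44-fold higher (108.6 against 38.6), and Tecpr1, which acts in autophagy, was at least 2.24-fold higher (99.9 against 18.2). The genes lowest under nicotine included the clock output factor Dbp (73.6 against 154.4, 2.10-fold lower) and the clock repressor Nr1d1 (95.4 against 195.9, 2.05-fold lower). Scarf2 was 2.25-fold lower, the phosphatase Dusp12 2.24-fold lower and the semaphorin receptor Plxna3 2.08-fold lower. For Icam1 and Tecpr1 the BN saline pool stood apart from the other 3 arrays, where Icam1 read 125.6 to 128.0 and Tecpr1 99.9 to 118.9. With means over all probe sets of a gene, the BN log2 ratios of Scarf2, Plxna3 and Tecpr1 shrank to -0.39, -0.58 and 0.58.

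Of 5366 genes measured in BN, 39 were at least 1.5-fold higher and 38 at least 1.5-fold lower, and 3 and 5 passed 2-fold. Next in size were Exd2, the import receptor Ipo7, the carbonyl reductase Cbr1, the glutaredoxin Glrx, Pde8a, Ankhd1 and Tmcc2, from 1.98-fold to 1.77-fold higher. On the lower side followed Las1l, the alanine transaminase Gpt, S100a13, Sertad1 and Raver1, from 1.93-fold to 1.80-fold lower. Of 8 markers of immune cells, 7 were higher under nicotine, with a median of 0.15 (percentile 99.4), RT1-Ba at 0.38, Laptm5 at 0.33 and Lyz2 at 0.26. Xenobiotic metabolism genes had a median of 0.07 (percentile 99.6), again led by Gstm1 at 0.37, with Gstm2 at -0.17. The 2 measured adipocyte markers, Thrsp at 0.40 and Lpl at 0.14, had a median of 0.27 (percentile 98.8). Proteasome genes were lower in 22 of 30 cases with a median of -0.049 (percentile 1.43); the largest ratios were 0.22 for Psmd9 and -0.20 for Psmc1. Of 29 lists, 4 lay outside the central range, against 1.45 by chance if genes and lists were independent. With means over probe sets the immune and adipocyte lists came to lie inside, at percentiles 95.8 and 88.2, and with the floor at the 20th percentile xenobiotic metabolism did, at 96.2.

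The circadian clock genes were 1 group in which several BN members were far apart. Of 7 measured members, 6 were lower in the nicotine pool and 3 were at least 1.5-fold lower: Dbp, Nr1d1 and Nr1d2, which read 154.7 against 277.6. The list's median of -0.079 lay at percentile 14.3, since the other members differed little. In SHR, the nicotine log2 ratio of Nr1d1 was 0.41 and that of Nr1d2 was -0.19.

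The angiotensin receptor gene Agtr1a read 179.4 against 161.3 in SHR and 150.0 against 138.2 in BN, nicotine against saline. Agt, which encodes angiotensinogen, read 83.1 against 104.5 in SHR and 89.9 against 65.2 in BN. The slit diaphragm gene Nphs1 read 83.8 against 90.6 in SHR and 86.4 against 90.7 in BN. Ace, Agtr1b, Agtr2 and Wt1 stayed below 89.0 on all 4 arrays, so a change in them was not detectable here. Of the genes for nicotinic and muscarinic receptors, only Chrna2 and Chrna7 reached that level on some array; in SHR they stood at 62.3 against 89.7 and at 97.3 against 72.4.

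How far the probe sets of a gene agree in these ratios can be read from genes with a second measured probe set. Each other measured probe set was paired with the brightest one of its gene, for 580 such genes in SHR and 577 in BN. The nicotine ratios of these pairs correlated with r = 0.045 and r = 0.15. The SD of a single probe set was estimated from the disagreement within pairs, as the SD of the difference divided by the square root of 2. It was 0.20 and 0.18, close to the 0.21 and 0.19 of all measured genes. Most of the spread of the nicotine ratios was thus not shared by the probe sets of a gene. For the strain ratios under saline and under nicotine, r was 0.259 and 0.30, and the SD of a single probe set was 0.309 and 0.305 against 0.362 and 0.361 over all measured genes. The same arrays entered both kinds of ratio, so the larger SD for strain is not array noise alone. It also holds strain differences that the probe sets of a gene do not share.

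Averaged over strains, a few genes kept the same direction in both. Pla2g12a, a secreted phospholipase, was 1.79-fold lower under nicotine in SHR and 1.96-fold lower in BN (148.1 against 264.8, and 44.8 against 87.6, the BN pair below the limit for a measured gene). Uchl1 was higher in both strains, with log2 ratios of at least 0.92 in SHR (84.4 against 7.2, below the limit for a measured gene) and at least 1.29 in BN. Plxna3 was 1.62-fold and 2.08-fold lower and the spliceosome helicase Snrnp200 1.51-fold and 1.67-fold lower. Qtrt1, which modifies transfer RNA, was 1.81-fold and 1.63-fold higher, and Meaf6 was 1.47-fold and 1.62-fold higher. The same rule named Rbmx, Stxbp2 and Rmi1 among the higher genes, and Elp6, Slain2 and the Polycomb partner Jarid2 among the lower ones. The kallikrein Klk1b3, near-identical to other kallikreins, and the glucocorticoid-induced factor Klf9 had log2 averages of 0.41 and -0.43 and were chosen after their values were seen.

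None of these genes passed the test over all genes. With limma, 0 of 5358 genes had an adjusted p under 0.05 for nicotine against saline, and 285 had an unadjusted p under 0.05 where chance gives 268. The smallest adjusted p was 0.0588, shared by Pla2g12a, Klk1b3 and Klf9, and it was 0.991 after quantile normalisation and 0.474 after cyclic loess. Adjusted over the list alone, 8 genes of the fixed lists passed. Slc9a3, the sodium-proton exchanger of the proximal tubule, fell by 0.38 on the log2 scale (SE 0.08, adjusted p over the list alone 0.0081 with limma), and the water channel Aqp2 fell by 0.35, with log2 ratios of -0.53 in SHR and -0.16 in BN. The clock gene Nr1d2 fell by 0.52, with -0.19 in SHR and -0.84 in BN. The macrophage lysozyme Lyz2 rose by 0.24, Gstm1 by 0.49, the oxidative stress regulator Nfe2l2 by 0.31, and in the matrix list Mmp14 rose by 0.73 (1.22 in SHR, 0.25 in BN) and vimentin, Vim, by 0.45 (0.16 in SHR, 0.75 in BN). The adjusted p over all genes for these 8 genes lay between 0.247 and 0.447, and with the floor at the 60th percentile 27 genes passed over all genes.

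The nicotine ratios of the 2 strains were unrelated across genes: Pearson r was -0.029 and Spearman rho -0.045 over 5697 genes, which are not independent replicates, and 48.4% of genes had the same direction. At 1.5-fold, 1 gene was higher in both strains and 3 were lower in both, where independent lists would share 0.19 and 0.15, and 1 was higher in SHR and lower in BN against 0.19.

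**Figure D1:**
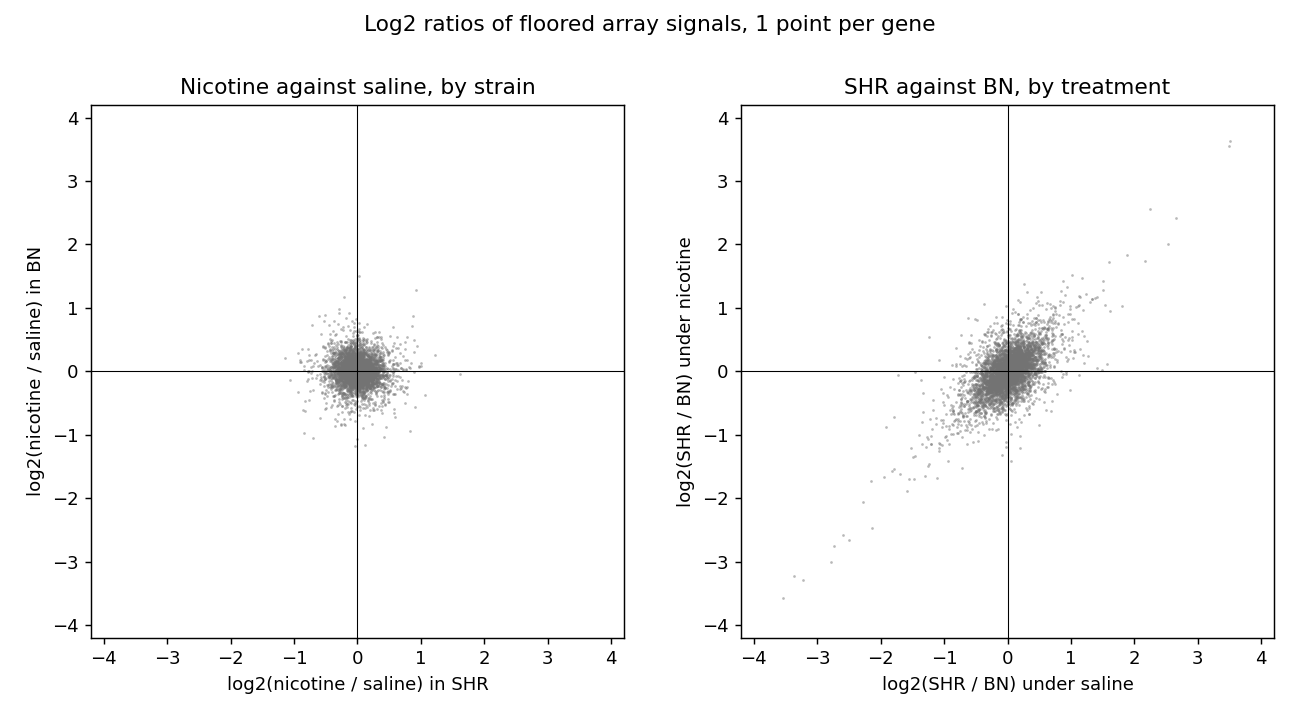
Each point is 1 of 10411 genes with floored signals, of which those measured on at least 1 array are drawn, and both axes are log2 ratios. On the left the nicotine ratios of SHR and BN form a round cloud (r = -0.029), and on the right the strain ratios under saline and under nicotine lie along the diagonal (r = 0.668).

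The strains themselves differed in many genes. Acsm3, a medium-chain acyl-CoA synthetase, was 11.9-fold higher in SHR (log2 3.57, SE 0.10, adjusted p = 3.64e-16 with limma), at 1059.8 and 873.1 in the SHR pools against 85.4 and 77.1 in the BN pools. Echdc2, of the enoyl-CoA hydratase family, was at least 11.5-fold higher in SHR. Acox2 and Cyp8b1, both enzymes of bile acid synthesis, were 5.29-fold and at least 4.82-fold higher, and the lactate and pyruvate carrier Slc16a1 was 2.68-fold higher. In the other direction, Rbp4, the carrier of retinol, was at least 11.7-fold lower in SHR, at 35.6 and 16.8 against 529.5 and 515.5. The phosphate and urate carrier gene Slc17a3 was at least 9.56-fold lower and the organic anion carrier gene Slc22a13 at least 5.98-fold lower. Gnmt, which consumes S-adenosylmethionine, was 3.85-fold lower, and Ptgds, a prostaglandin D2 synthase, 3.51-fold lower.

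With limma, 959 of 5444 genes differed between strains averaged over treatments, 451 higher and 508 lower in SHR, and 1651 had an unadjusted p under 0.05 where chance gives 272. Of the 959, 957 had the same direction under both treatments and 78 were at least 2-fold apart, 32 higher and 46 lower. The agreement in direction is largely fixed by selecting genes on the average of the same ratios. Counted by size, 49 genes were at least 2-fold higher and 62 at least 2-fold lower in SHR under saline, and 49 and 53 under nicotine. Both treatments shared 25 of the higher and 36 of the lower genes, where independent lists would share 0.34 and 0.49, and no gene past 2-fold was opposite. The strain ratios under saline and under nicotine correlated across genes with r = 0.668. The limma count depends on the model: it was 498 after quantile normalisation, 440 without the intensity trend and 0 with no filter on low genes. The smallest adjusted p with limma was 0.000117, 4.33e-05 and 0.274 in these alternatives, against 3.64e-16 as reported. With the floor at the 60th percentile it was 8.56e-41, so its size depends on the processing. Without SHR nicotine, SHR saline, BN nicotine or BN saline it was 574, 598, 314 and 306; these fits had strain as the only factor, which with all 4 arrays gave 770.

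**Figure D2:**
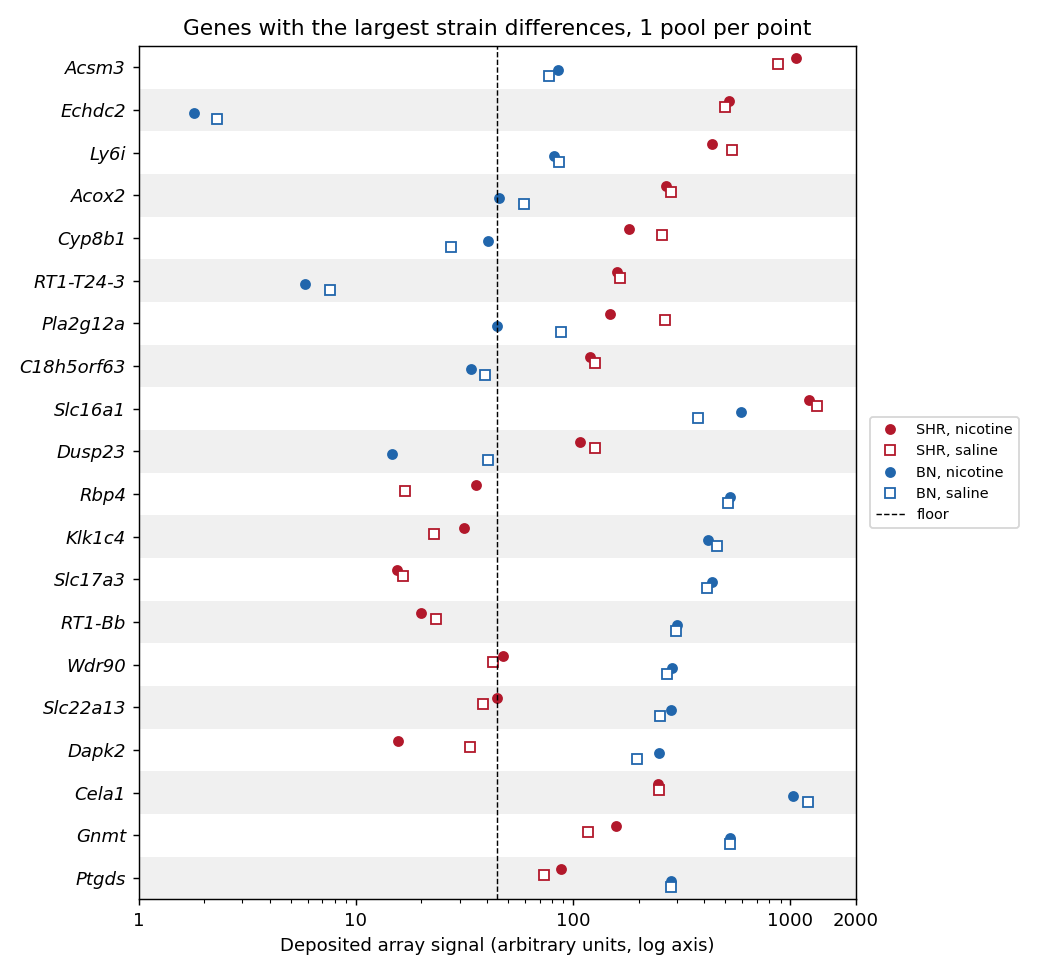
Deposited signal on each of the 4 arrays, on a log axis, for the 10 genes with the largest difference in each direction, with 1 pool per point and the floor of 44.5 as a dashed line. For Acsm3 the SHR pools read 1059.8 and 873.1 against 85.4 and 77.1 in the BN pools.

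Completing the genes with the largest strain differences, Ly6i, Pla2g12a, C18h5orf63 and Dusp23 were higher in SHR by 5.78-fold, 3.16-fold, at least 2.77-fold and at least 2.62-fold. The class I gene RT1-T24-3 was at least 3.64-fold higher. Lower in SHR were Klk1c4 (at least 9.83-fold), the class II gene RT1-Bb (at least 6.71-fold), Wdr90 (at least 6.03-fold), the kinase Dapk2 (at least 4.96-fold) and the elastase Cela1 (4.50-fold). Klk1c4, Ly6i and the RT1 genes belong to families of near-identical or highly variable genes, so their probe sets may read different family members in each strain. Ythdf2 and Ogn were left out because another probe set of the gene differed in direction under saline.

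Enzymes of xenobiotic metabolism were lower in SHR as a group. Of 20 genes tested, 12 passed over all genes, 10 lower and 2 higher, and 15 passed adjusted over the list alone. Among all genes 959 of 5444 passed, so a list count near that share does not set the list apart, here or below. Whether any list held more than that share was not tested. Gstm1 was 3.17-fold lower, Cyp2d2 2.63-fold, Gstm2 1.89-fold and the sulfotransferase Sult1a1 1.88-fold, all from families with near-identical members. The list's median was -0.44 under saline and -0.32 under nicotine, below all 10000 random lists both times. Ribosomal protein genes were lower by small amounts: 12 of 41 passed, 11 of them lower, 18 adjusted over the list alone, with medians of -0.18 and -0.10, and Rps16 and Rps23 were 1.32-fold and 1.31-fold lower. The 3' to 5' signal ratio of beta-actin, a sign of RNA integrity, also went with strain, at 1.34 and 1.39 in SHR and 1.49 and 1.54 in BN. That of Gapdh did not, at 1.11 and 1.0 in SHR and 1.09 and 1.07 in BN. An effect of RNA integrity on the small ribosomal shift was not tested. Heat shock and unfolded protein response genes were higher: 5 of 23 passed, all higher in SHR, 10 adjusted over the list alone, with medians of 0.21 and 0.13. The chaperones Hspa5, Hsp90b1 and Calr of the endoplasmic reticulum were 1.55-fold, 1.48-fold and 1.35-fold higher.

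Of 9 SHR candidate genes 6 passed, 6 adjusted over the list alone, 2 higher and 4 lower; the higher are Acsm3 and Ogn, and the probe sets of Ogn disagree. Cd36, the fatty acid carrier that is defective in many SHR colonies, was 3.33-fold lower in SHR, and Gstm1 3.17-fold lower. In eicosanoid metabolism 6 of 12 passed (8 over the list alone), with Cyp4a8 2.29-fold higher and Ptgds and Cyp2c11 lower. In fatty acid oxidation 5 of 26 passed (6 over the list alone), with Cyp4a8 first and Ehhadh 1.40-fold lower, and in cholesterol and fatty acid synthesis 7 of 17 (8 over the list alone), with Fasn 1.66-fold higher and Lss 1.89-fold lower. In insulin and growth factor signalling 5 of 18 passed, the same 5 over the list alone, with Igf1 1.57-fold and Igfbp3 1.53-fold higher and Pik3r1 at least 2.15-fold lower.

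Among markers of kidney segments, 10 of 20 proximal tubule genes passed, 7 higher and 3 lower (13 over the list alone), with Slc17a3 at least 9.56-fold and the endocytic receptor Cubn 1.48-fold lower and Slc9a3 1.33-fold higher. In the loop of Henle and distal convoluted tubule, 3 of 9 passed (3 over the list alone): Slc12a1, the target of loop diuretics, was 1.7-fold lower, Slc12a3 1.25-fold lower and Umod 1.30-fold higher. In the collecting duct, 4 of 12 passed (9 over the list alone), with Fxyd4 1.69-fold lower, the anion exchanger Slc4a1 1.34-fold higher and Aqp2 1.33-fold lower; of the 9, 4 were higher and 5 lower. The podocyte list had 1 of 9, Podxl at 1.47-fold lower. Of 9 immune cell markers 8 passed (9 over the list alone): the macrophage genes C1qa and Lyz2 were 1.88-fold and 1.7-fold higher, while RT1-Bb and RT1-Db1 were lower. Endothelial markers had 3 of 10, with Vwf at least 3.0-fold lower and Esam and Kdr 1.35-fold and 1.25-fold higher, and smooth muscle markers 2 of 6, Smtn and Mylk, 1.46-fold and 1.26-fold higher. Markers of adrenal gland and skeletal muscle were not measured on any array.

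In oxidative phosphorylation 12 of 69 passed (12 over the list alone), 8 higher and 4 lower in SHR, with Ndufb8, Sdha and Ndufv3 1.52-fold, 1.32-fold and 1.30-fold lower and Ndufa4 1.26-fold higher. In antioxidant defence 6 of 27 passed (10 over the list alone), with the heme oxygenase Hmox2 1.43-fold and the NADPH oxidase Nox4 1.39-fold higher. In apoptosis 4 of 12 passed, with the inhibitor Birc2 higher by 0.68 and Bnip3 lower by 0.50 on the log2 scale, and in the cell cycle 2 of 8, Cks2 and Ccnd1, both lower. Of interferon and antigen presentation genes 6 of 13 passed (8 over the list alone), 4 higher and 2 lower: on the log2 scale the interferon regulator Irf7 was higher by 0.89 and the virus-restricting Bst2 by 0.51, while the class II genes RT1-Bb and RT1-Db1 stood at -2.75 and -0.71. The proteasome list had 2 of 31, Psmc5 and Psma1, both lower, the adipocyte list 1 of 2, Lpl, lower, and the blood list 0 of 2.

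For blood pressure, 2 of 9 genes of the angiotensin system passed, both higher in SHR: the aminopeptidases Anpep at 1.68-fold and Enpep at 1.27-fold. Agtr1a was higher by 0.24 on the log2 scale and did not pass (SE 0.13, adjusted p = 0.209 with limma). Of 9 vasoactive genes, Klk1 was 1.39-fold and Sgk1 1.20-fold lower. In the matrix and fibrosis list, 5 of 21 passed (6 over the list alone), all 5 higher in SHR, with Col3a1 at 1.64-fold and Ccn2 at 1.59-fold. The share among all genes was 959 of 5444. In nephron development 3 of 8 passed, with Gfra1 1.56-fold and Jag1 1.54-fold higher and Bmp7 1.26-fold lower.

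The clock list's median was -0.45 under saline (percentile 0.04) and 0.006 under nicotine (percentile 48.6), and 4 of 9 genes passed (6 over the list alone), among them Dbp, at least 2.39-fold lower in SHR, and Nr1d1, 1.67-fold lower. The Nr1d1 difference lay under saline, at 71.2 in SHR against 195.9 in BN, while under nicotine the gene read 94.7 against 95.4. Early response genes had medians of -0.35 (percentile 0.01) and -0.15 (percentile 8.68), with means of -0.13 and -0.17, and the saline position was 14.2 with the floor at the 20th percentile and 3.0 with means over probe sets. Whether either list differed more under saline was not tested. Of the early response genes 3 of 10 passed (4 over the list alone), with Dusp1 1.63-fold lower and Jun 1.38-fold higher.

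**Figure D3:**
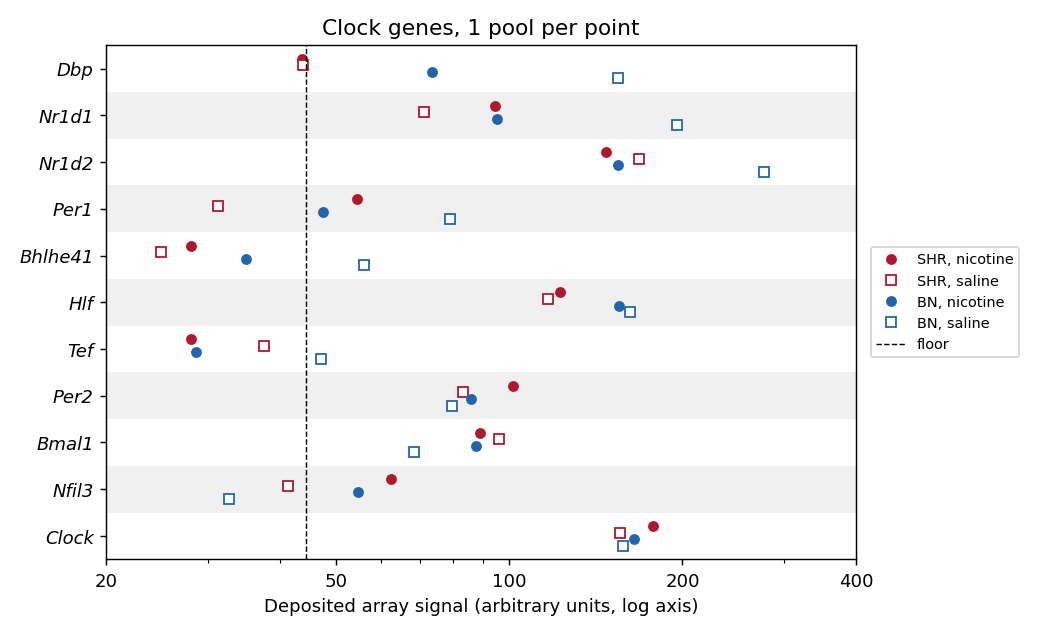
Deposited signal of 11 clock genes on each of the 4 arrays, on a log axis, with 1 pool per point and the floor of 44.5 as a dashed line. Dbp, Nr1d1 and Nr1d2 read 154.4, 195.9 and 277.6 in the BN saline pool, above the other 3 arrays, and Bmal1 read 68.4 there, below them.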

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

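All values here are differences of log2 ratios from single pools, the differences between strains were not tested, and no test in this part was chosen after the result was seen. By the fixed rule, 10 genes were taken because nicotine and saline stood in opposite order in the 2 strains. The transcription factor gene Stat5a had a nicotine log2 ratio of 0.60 in SHR and -0.72 in BN, a difference of 1.31. The histone deacetylase gene Hdac3 stood at 0.57 and -0.60, a difference of 1.17, and the mitochondrial ribosome gene Mrpl1 at 0.91 and -0.56, a difference of 1.47. Ifi27l2b and the chromatin remodelling gene Smarcd2 followed with differences of 0.98 and 0.95. In the other direction, the replication helicase gene Mcm7 stood at -0.52 in SHR and 0.80 in BN, a difference of -1.32, and the glutaredoxin gene Glrx at -0.51 and 0.89, a difference of -1.41. Marcks differed by -1.18, the beta globin gene Hbb by -1.01 and Eif2s3 by -0.87. With means over probe sets the order of Marcks was no longer opposite, at 0.04 in SHR and 0.26 in BN, and Glrx shrank to -0.18 and 0.47. Hbb is near-identical to other globin genes and reads blood left in the tissue; it stood at 824.5 and 1111.7 in the SHR nicotine and saline pools and at 1310.6 and 876.9 in the BN pools.

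Probe sets without a single gene symbol were outside all comparisons of named genes. Among the 921 of them measured in both strain comparisons, 28 were at least 2-fold apart between SHR and BN in the same direction under both treatments, 21 higher and 7 lower in SHR. For nicotine against saline, 2 such probe sets were at least 2-fold apart in SHR and 4 in BN.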

How the results depend on the processing

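All alternatives in this part were planned before the data were examined. No paired analysis was possible because the labels carry no replicate numbers and each group is a single pool. This concerns pairs by replicate number, since the additive model does compare the treatments within each strain. Scaling changed little: under quantile normalisation, median centring and cyclic loess, every count of genes at least 2-fold apart stayed within 1.5 times its value. With the floor at the 20th percentile the counts at 2-fold became 171 for nicotine in SHR, 129 for nicotine in BN, 309 for strain under saline and 286 under nicotine, and with the floor at the 60th percentile 1, 1, 60 and 53. With log2(value + 16) the nicotine counts were 2 in SHR and 3 in BN. A 1.5-fold threshold gave 102, 77, 406 and 419 genes and a 3-fold threshold 1, 0, 27 and 25, by their construction. In BN, the mean over probe sets gave 5 genes and counting probe sets gave 13. For the strain average, limma found 959 genes as reported, 498 after quantile normalisation, 440 without the intensity trend and 0 with no filter on low values, where 1280 still had an unadjusted p under 0.05; 497 of the 498 and 421 of the 440 were among the 959. Leaving out 1 array, with strain as the only factor and the lone pool assumed to vary like the others, gave 306 to 598, against 770 for that model with all 4 arrays. For the nicotine average, limma found 6 genes with the floor at the 20th percentile, 27 with the floor at the 60th and 4 with log2(value + 16), against 0 as reported, and 0 in the other alternatives, where the smallest adjusted p was 0.991 after quantile normalisation, 0.474 after cyclic loess, 0.235 with means over probe sets and 0.189 without the trend; the cause was not tested. Pla2g12a, Uchl1, Klf9 and Klk1b3, of which the last 2 were named after their values were seen, made up the 4 and were also among the 6. The correlation of nicotine ratios between strains was 0.016 with the floor at the 20th percentile and between -0.031 and -0.019 otherwise. Of 77 nicotine ratios of named genes under each of 4 alternatives, 1 reversed: Marcks in SHR was 0.04 with the mean over probe sets; the cause was not tested. Another 10 moved by more than the SD of a single probe set: with the mean over probe sets Grm8 in SHR was -0.29, Glrx -0.18 in SHR and 0.47 in BN, and in BN Scarf2 was -0.39, Plxna3 -0.58, Tecpr1 0.58 and Marcks 0.26, while with the floor at the 20th percentile Icam1, Uchl1 and Tecpr1 in BN were 2.77, 1.49 and 2.46. Of 475 list medians in the same alternatives, 9 left their bootstrap interval. Of the 5 lists outside the central 95% in SHR, 3 or 4 stayed outside in each alternative, and of the 4 in BN, 2 to 4. For strain 6 to 10 of 10 stayed outside under saline and 7 of 8 under nicotine. The 20 named strain differences kept their direction and stayed past the threshold in all 4 alternatives. None of these genes had another measured probe set under saline, so the mean over probe sets gave no second measured reading of them. Genes below the floor, among them most nicotinic receptor genes, have too little signal over background for any ratio.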

Other observations

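The tests of a shared nicotine response, of the clock and of the other probe sets of genes called between strains were chosen after the result was seen; the tests of single probe sets on 2-fold strain genes and on nicotine ratios were planned. Beyond the comparisons above, several kidney genes with bright signals had close nicotine ratios in both strains. Slc9a3 stood at -0.38 in SHR and -0.39 in BN, Klf9 at -0.47 and -0.39, and Klk1b3 at 0.44 and 0.39. Nfe2l2 stood at 0.27 and 0.34, Atp6v1b2, a proton pump subunit, at -0.28 and -0.28, and Micu2, a regulator of mitochondrial calcium uptake, at -0.52 and -0.37. By contrast, C1qbp at 1.0 in SHR and 0.09 in BN had the smallest adjusted p of the nicotine average with the floor at the 60th percentile (3.32e-07 with limma), although its difference lay in SHR alone. These genes were chosen after their values were seen.

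The strain differences were weighed against sequence variants under the probes, on the premise that a variant lowers the signal of only 1 probe set of a gene. Variants under several probe sets of a gene would escape this test. For the 61 genes at least 2-fold apart in the same direction under both treatments, only 4 had another measured probe set, with a signed median of 0.40 and a bootstrap interval from -0.96 to 1.72, so the explanation cannot be told apart for them. Among these, Ythdf2 read 7.46-fold lower in SHR on its brightest probe set and 0.17 in the signed log2 value on the other. Rab14, named after its values were seen, had a log2 difference of -1.14 and a signed value of -0.96 on the other, against the called direction. The signed values of Cyp4a8 and Ogn were 1.72 and 0.62. Of the genes past the threshold, 112 had other measured probe sets, and for 96 of these genes they shifted in the called direction on average. For 78 genes all of them moved in the called direction under both treatments. Over all 112 genes, the other probe sets had a signed median of 0.24 (interval 0.20 to 0.30), against 0.39 for the called probe sets. On the premise above, this argues against variants as the whole cause for that set. A difference in expression between strains is left open as a hypothesis, and single genes such as Ythdf2 and Rab14 may still be probe effects.

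Nicotine ratios of at least 1.5-fold were set against noise of single probe sets and against a response shared by the strains. Only 5 of 102 such genes in SHR and 5 of 77 in BN had another measured probe set. The other probe sets had signed medians of 0.01 (interval -0.73 to 0.60) and 0.14 (interval -0.17 to 0.68). With so few genes, noise cannot be excluded or shown for the genes past 1.5-fold. Over all genes with a second measured probe set, the ratios of pairs correlated with r = 0.045 in SHR and 0.15 in BN. Most of the spread of nicotine ratios was therefore not shared by the probe sets of a gene. Of the genes past 1.5-fold, the 65 of SHR also measured in BN had a median of 0.04 there (interval -0.07 to 0.10). The 53 of BN measured in SHR had -0.02 (interval -0.12 to 0.04), against 0.70 and 0.72 in the strain of origin. For these genes as a set, the values argue against a shared response of that size. They do not bear on a shared response of a few genes, and genes picked through noise would give such medians as well. At 1.5-fold, 1 gene was higher and 3 were lower in both strains, where independent lists would share 0.19 and 0.15. In opposite directions, 1 was higher in SHR and lower in BN against 0.19, and 0 the reverse against 0.14. A response that differs between strains and differences between pools other than nicotine may both account for the genes and stay open.

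Of 8 clock genes of one phase at or above the floor, 7 were highest in the BN saline pool. Among these, Dbp, Nr1d1 and Nr1d2 had raised the question, and Tef, Per1 and Bhlhe41 did not reach 89.0 on any array. Hlf read 162.1 in the BN saline pool against 155.2 in the BN nicotine pool. Of the 3 genes of the opposite phase 2, Bmal1 and Nfil3, were lowest there. Nfil3 read 32.6 there and 41.4 in the SHR saline pool, both below the floor, so its order is not stable. Both bright probe sets of Nr1d2 moved alike, with log2 ratios of -0.84 and -0.68. Without Dbp, Nr1d1 and Nr1d2, which raised the question, the opposite phase minus the first, nicotine against saline in BN, was 0.46 (percentile 99.5 of random draws), but 0.19 (percentile 77.2) over the 4 remaining genes that reached 89.0, so a difference in clock phase between the BN pools when tissue was taken cannot be told apart from other causes. In SHR the score over the 6 measured clock genes was -0.10, against 0.67 for the same genes in BN and an upper random bound of 0.49, but without Nr1d1 and Nr1d2 it was -0.14 against 0.19 with a bound of 0.58. A clock change with nicotine shared by the strains therefore cannot be told apart either, with so few measured genes. The labels give no time of day, and a nicotine effect on the clock in BN alone stays open and untested.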
